A study of Homo sapiens with 24 samples.

How the data were processed

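Total RNA was measured on 24 Illumina human expression BeadChips, each read from biotin-labelled cRNA. The samples came from mice carrying UM-UC3, an established human urothelial (bladder) cancer cell line that was passed through the bladder of mice repeatedly. Per the labels, 6 arrays each came from primary tumors, lymph node metastases, distant metastases (of lung and bone, without a label saying which array came from which organ) and circulating tumor cells (CTCs). The design text speaks of 5 tumors per tissue, while the labels list 6 samples in each group, and the labels were followed. RNA was extracted with a mirVana kit and its quality checked by NanoDrop and Bioanalyzer, per the labels' protocols.

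The values used were the log2 expression values that the authors deposited as their processed table, with 47323 probes per array. These values were already quantile normalized: the sorted values of any 2 arrays differed by at most 0.0022, and each array had a median of 5.93, quartiles of 5.68 and 7.34, a minimum of 4.90 and a maximum of 15.37. The base of the logarithm was taken as 2, since the highest value then corresponds to a linear intensity of 42232.9, within the range of such a scanner. The values were not centred per gene. The submitters' processing notes name limma, without a version, and the background correction is not given in the sources used here, so changes near the bottom of the scale can be compressed. A second table with 24 signal and 24 detection p columns, 48 in all, was not used here, since its columns are headed by a running number that no label matches to a sample. The design fixed in advance assumed background-corrected signals with detection p-values, or, if the signals were already normalized, the values as they are, and the latter applied. All probes were therefore tested without a filter on dim probes.

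Of the 47323 probes, 30113 were paired with 1 gene symbol by the array annotation, 8 with several and 17202 were not listed, which gave 20046 distinct symbols. Symbols were compared with a current gene table and 0 needed a change. A gene was represented by its probe of highest mean over all arrays. Human probes can also bind RNA of the mouse host, and the processed values give no way to separate the species.

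A linear model was fitted per probe with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 24 arrays (20 residual degrees of freedom) and empirical Bayes moderation. Tests were two-sided. P-values were adjusted by the Benjamini-Hochberg method within each of the 6 comparisons between groups, with a threshold of 0.05, and an F test asked for any difference among the 4 groups. In all, 39 gene lists were fixed, of pathways, tumor cell states and host cell types, and were tested with limma's camera (preset correlation 0.01), with adjustment over all lists and comparisons together. Camera with an estimated correlation and fry were run beside it. Fry asks whether the genes of a list move, on balance, one way, and its mixed version whether they change in either direction. Neither compares the list with other genes. Similarity between arrays was the mean Spearman correlation within groups minus that between groups, with a permutation test of 100000 resamples. Errors are SDs over 6 arrays for group means and standard errors for log2 changes. Figures were drawn with matplotlib 3.10.9 under python 3.11.15, and jsonlite 2.0.0 read the labels.

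The labels number the mice 1 to 6 in every group, so the arrays of a number were taken as paired by mouse. As a check, the deviations of same-numbered arrays from their group means had a mean correlation of 0.138 across probes, against -0.0253 for other arrays of different groups (difference 0.164, permutation p = 0.0099). For 16 of the 24 arrays the closest array of another group carried the same number. The correlation of same-numbered arrays ranged from 0.307 to 0.622 between CTCs and distant metastases and fell below 0 for some pair in each of the other comparisons. Its mean was 0.417 between CTCs and distant metastases. Against primary tumors it was 0.241 for distant metastases, 0.159 for lymph node metastases and 0.0549 for CTCs. Against lymph node metastases it was 0.0183 for distant metastases and -0.06 for CTCs. The consensus correlation of arrays of 1 mouse was 0.0485, so the pairing is weak outside CTCs and distant metastases. The model without the mouse is reported first, and the model with the mouse number as a replicate block (15 residual degrees of freedom) is given where it moves a result. The arrays are separate samples per the labels, no pair of arrays held identical values, and the number of arrays limits the precision.

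The rule for naming genes was set in advance. In each comparison against the primary tumors, the 10 largest rises and the 10 largest falls among genes past the threshold were named, or, with fewer than 5 past it, the 10 smallest p-values. In the other comparisons the rule took 5 in each direction. Blank symbols, symbols that start with LOC or HS. and clone names were left out. For each list described, up to 4 members with the smallest adjusted p were named. Genes named outside the rule are said to have been chosen after their values were seen.

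The probe model and camera (with a single shifted list) were tested on simulated arrays with known changes, and the other steps were not. The simulated arrays took each probe's mean and residual SD from the real ones. Their noise was independent between arrays and probes and of equal spread in all groups. The real spread differed between groups for some probes, so the shares below need not hold for the real arrays. Of the 67 probes changed by 1 on the log2 scale in each comparison, the model recovered 86.6% for lymph node metastases against primary tumors, 89.6% for distant metastases against primary tumors, 92.5% for CTCs against primary tumors and 92.5% for distant against lymph node metastases. The shares were 83.6% for CTCs against lymph node metastases and 88.1% for CTCs against distant metastases. Of the 67 changed by 0.5, it recovered 50.7% for lymph node metastases and 70.1% for distant metastases against primary tumors. It recovered 62.7% of them for distant against lymph node metastases. For CTCs these shares were 56.7%, 61.2% and 62.7% against primary tumors, lymph node and distant metastases. Changed probes were drawn at random from all probes, so the shares need not hold for probes of wide spread. In the real arrays IGFBP3 (log2 change -1.89, SE 0.40) and NGEF (0.95, SE 0.20) did not pass for lymph node metastases against primary tumors. Smaller changes, and larger ones of variable probes, can thus be missed where 0 probes were called. Other choices tried were the replicate block (fixed and random), trend and robust variance, array weights, models of only the groups compared, a filter on dim probes, cyclic loess normalization, a fold threshold, the mean of a gene's probes, each array left out in turn, all arrays of mouse 5 left out, and the HBA2 probe as a covariate.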

Results

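Expression was measured in UM-UC3 bladder cancer cells grown as tumors in mice, in 6 primary tumors, 6 lymph node metastases, 6 distant metastases of lung and bone and 6 samples of circulating tumor cells (CTCs). The question of the design is which genes differ between the primary tumor, the places it spread to and the cells in transit in the blood. All values are normalized log2 intensities, on a scale whose median was 5.93 on each array. Pooled over groups, arrays of 1 group were slightly more alike than arrays of different groups: the mean Spearman correlation was 0.8911 within groups and 0.8873 between them (difference 0.0038, permutation p = 0.00235), while with Pearson's r the difference was 0.0015 (permutation p = 0.105). The means within groups were 0.8999 for CTCs, 0.8923 for distant metastases, 0.8873 for primary tumors and 0.885 for lymph node metastases, and the last 2 lay below the 0.8878 between primary tumors and lymph node metastases. The F test over the 4 groups called 402 of 47323 probes (880 with the mouse number as a replicate block). Without primary replicates 2 and 3 and lymph node replicate 3 it called 267, 258 and 250, and without CTC replicates 1, 3, 4 and 6 it called 170, 833, 161 and 150.

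The comparison of CTCs with primary tumors asks which genes differ between the cells in the blood and the solid tumor. Circulating cells and solid tissue are also different kinds of sample, which the comparison cannot separate from being in the blood. The largest rise in CTCs was that of COXFA4L3, which encodes a mitochondrial protein related to a subunit of cytochrome c oxidase, to 10.62 ± 0.74 (SD, n = 6; log2 change 2.62, SE 0.51, adjusted p = 0.00971). CGB1, of the chorionic gonadotropin beta family, rose from 5.98 ± 0.23 to 8.08 ± 0.56 (log2 change 2.10, SE 0.24, adjusted p = 0.000182), and the neutrophil-attracting chemokine CXCL2 rose from 6.52 ± 0.99 to 8.43 ± 0.22 (log2 change 1.91, SE 0.38, adjusted p = 0.011). The matrix protein gene TGFBI, the transferrin receptor gene TFRC and SMAD6, an inhibitor of BMP signaling, rose by log2 changes of 1.88, 1.87 and 1.87 (adjusted p = 0.00107, 0.00418 and 0.0135). IER3, the receptor gene P2RY8, the ErbB ligand gene NRG1 and XYLT1, an enzyme of proteoglycan synthesis, rose by log2 changes of 1.86, 1.80, 1.65 and 1.60 (adjusted p = 0.0335, 0.015, 0.034 and 0.0207). Each of these 10 genes was higher in 6 of 6 mice, except IER3 in 5 of 6. CGB1, CGB5 and LHB are near-identical copies, so which of them the CGB1 probe reads is uncertain. The smallest p of all probes was that of a CGB5 probe, named after its values were seen, which rose by 2.42 (adjusted p = 6.21e-05, higher in 6 of 6 mice), while the CGB5 probe of higher mean had a log2 change of -1.12 (adjusted p = 0.1).

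The largest falls in CTCs were those of the lipoprotein gene APOE, from 10.96 ± 2.41 to 6.72 ± 0.76 (SD, n = 6; log2 change -4.25, SE 0.98, adjusted p = 0.0244), the matrix-associated gene SPARCL1 (log2 change -3.11, adjusted p = 0.0385) and JUP, which encodes the junction protein plakoglobin (log2 change -2.73, adjusted p = 0.0293). SLITRK3, DENND2A and the interferon-induced gene IFI6 fell by 2.19, 1.98 and 1.92 on the log2 scale (adjusted p = 0.00785, 0.0206 and 0.00555). CA11, the glutathione transferase gene GSTO2, the pseudokinase gene TRIB2 and the synaptic scaffold gene DLG4 fell by 1.91, 1.88, 1.85 and 1.84 (adjusted p = 0.025, 0.0102, 0.0088 and 0.0276). By the sign of the difference all 10 were lower in 6 of 6 mice, but in mouse 5 SPARCL1 lay at 5.83 in both groups. The probe of HBA2, a hemoglobin gene of red cells, lay at 11.78 ± 2.88 in primary tumors and 8.03 ± 2.55 in CTCs (log2 change -3.76, adjusted p = 0.284), lower in 6 of 6 mice, and with the replicate block it passed (adjusted p = 0.0323). In the primary tumor of mouse 5, APOE, SPARCL1, JUP and HBA2 lay at 6.76, 5.83, 6.15 and 6.20. In the CTCs of that mouse they lay at 6.51, 5.83, 5.70 and 5.84. HBA2 in mouse 2 lay at 12.67 in the primary tumor and 12.43 in CTCs. The other SPARCL1 probe, with a log2 change of -0.28, and the 2 other JUP probes, with -0.40 and -0.49, did not pass (adjusted p = 0.146, 0.0905 and 0.149), nor did the other HBA2 probe (log2 change 0.17, adjusted p = 0.537). The second probes of IFI6, CGB1 and XYLT1 did not pass either, with log2 changes of -0.75, 0.02 and 0.05 (adjusted p = 0.129, 0.959 and 0.783). Of the other probes of COXFA4L3 and NRG1, 1 each rose, by 1.38 and 1.39 (adjusted p = 0.016 and 0.0313), and 1 and 5 did not pass.

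Limma called 929 probes between CTCs and primary tumors, 556 higher and 373 lower in CTCs, in 326 and 273 genes, and the replicate block gave 1659 probes (943 higher and 716 lower). The share of higher calls depended on the processing. It was 59.8% here and 52.8% with the trend and robust variance model (387 higher and 346 lower of 733). After cyclic loess of the already normalized values it was 42.6% (367 higher and 495 lower of 862). Among calls with a log2 change of at least 1, 62 were higher and 146 lower. With only the 12 arrays of these groups in the model the count was 163, and of the 20 named genes CGB1, TGFBI, TFRC and IFI6 still passed. Without primary replicates 1, 2, 3 and 4 the count was 484, 473, 399 and 600, and without CTC replicates 1, 3, 4 and 6 it was 513, 1662, 568 and 503. Without primary replicate 3, the calls of IER3, NRG1, XYLT1, APOE, SPARCL1, JUP, DENND2A, CA11 and DLG4 ended. Most of these calls ended without other arrays too. Of 12 runs with 1 array left out, SPARCL1 passed in 2, NRG1 in 3, IER3 and JUP in 4 and APOE in 6. CA11 and DLG4 passed in 7, DENND2A in 8 and XYLT1 in 11. With HBA2 as a covariate the count was 530, and 10 of the 20 named genes no longer passed. These were SMAD6, IER3, P2RY8, NRG1 and XYLT1 among the rises and APOE, SPARCL1, JUP, DENND2A and CA11 among the falls. APOE then had a log2 change of -2.52 (adjusted p = 0.0903) and SPARCL1 one of -1.69 (adjusted p = 0.147).

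**Figure D1:**
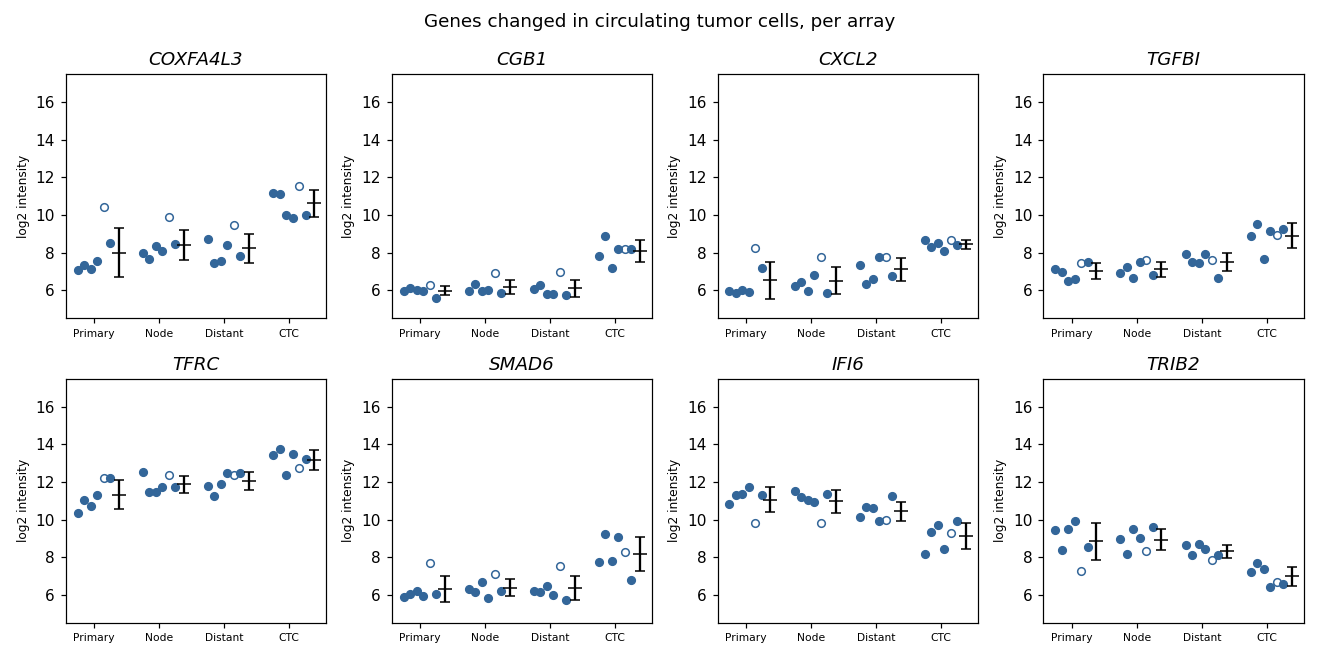
Log2 intensity per array (vertical axis) of 8 genes named for CTCs, for primary tumors, lymph node metastases, distant metastases and CTCs (n = 6 each); dots are arrays, open circles the arrays of mouse 5, and black marks the mean ± SD. COXFA4L3, CGB1, CXCL2, TGFBI, TFRC and SMAD6 have a higher mean in CTCs than in each solid group, and IFI6 and TRIB2 a lower one.

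The interferon response list fell in CTCs: of 27 genes measured, 0 rose, 3 fell and 24 did not pass (10 fell when adjusted over the list alone). IFI6, IFIT1 and IFIT2, which are induced by interferon, fell by 1.92, 1.44 and 0.93 on the log2 scale (adjusted p = 0.00555, 0.0156 and 0.017), and the list's adjusted p was 5.4e-06 (adjusted p = 0.707 with an estimated correlation). The antigen presentation list also fell. Of 19 genes measured, TAPBP, B2M and PSMB8 fell by 1.24, 0.62 and 1.36 (adjusted p = 0.0112, 0.0212 and 0.0406) and 16 did not pass, while 9 fell when adjusted over the list alone. That list's adjusted p was 0.000362 (adjusted p = 0.707 with an estimated correlation). For CTCs fry called 2 lists against primary tumors, 3 against lymph node metastases and 1 against distant metastases. Of these 6 calls 5 were up and 1 was down. Thus at most 1 of the falls of the interferon and antigen presentation lists in the CTC comparisons passed fry. Of 19 host myeloid markers, the complement gene C1QB, at the bottom of the scale, fell by 0.35 on the log2 scale (adjusted p = 0.0444). The macrophage gene AIF1 had a log2 change of -2.02 (adjusted p = 0.0591; 0.00455 with the replicate block, lower in 6 of 6 mice), and C1QA one of -0.66 (adjusted p = 0.15; 0.0451 with the replicate block). CORO1A, of the 17 host leukocyte markers, had a log2 change of -1.04 (adjusted p = 0.0847; 0.0344 with the replicate block). Neither list passed (adjusted p = 0.561 for myeloid and 0.931 for leukocyte markers), and 2 myeloid and 1 leukocyte markers fell when adjusted over the list alone. The leukocyte median log2 change was 0.01 and the mean -0.02. The mean of the myeloid list was 6.41 ± 0.12 in primary tumors and 6.24 ± 0.07 in CTCs (SD, n = 6).

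The TGF-beta pathway list rose in CTCs: 5 of 23 genes rose, 0 fell and 18 did not pass, while 11 rose and 1 fell when adjusted over the list alone. TGFBI, SMAD6, CCN1 and SMAD7 rose by log2 changes of 1.88, 1.87, 1.28 and 1.56 (adjusted p = 0.00107, 0.0135, 0.015 and 0.0215). The adjusted p of the list was 0.000362 (adjusted p = 0.225 with an estimated correlation). Among MYC target and nucleolar genes, 4 of 22 rose, 0 fell and 18 did not pass (7 rose when adjusted over the list alone). TFRC, DKC1, NPM1 and HSPD1 rose by 1.87, 0.55, 0.24 and 0.70 (adjusted p = 0.00418, 0.0241, 0.0375 and 0.0407), with NPM1 read by a dim probe at 6.05 ± 0.07 in CTCs (SD, n = 6). The MYC list's adjusted p was 1.03e-05 (adjusted p = 0.342 with an estimated correlation).

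The cell cycle list rose, with AURKA and CENPE past the threshold (log2 changes 0.63 and 0.76, adjusted p = 0.037 and 0.0465) and 28 of 30 not passing. Adjusted over the list alone 8 rose, and the list's adjusted p was 3.5e-05 (adjusted p = 0.791 with an estimated correlation). Of 24 NF-kB and cytokine genes only CXCL2 passed over all probes (log2 change 1.91, adjusted p = 0.011), and 3 rose when adjusted over the list alone. The adjusted p of that list was 0.0405 (adjusted p = 0.707 with an estimated correlation), and it rose to at most 0.135 with 1 array left out, the call ending without primary replicates 1, 2, 3 and 4 and CTC replicates 2, 5 and 6. Epithelial junction genes (1 of 21 fell, JUP; 3 fell when adjusted over the list alone) and mesenchymal genes (1 of 19 rose, TGFBI; 2 rose and 3 fell when adjusted over the list alone) did not pass as lists (adjusted p = 0.561 and 0.917).

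**Figure D2:**
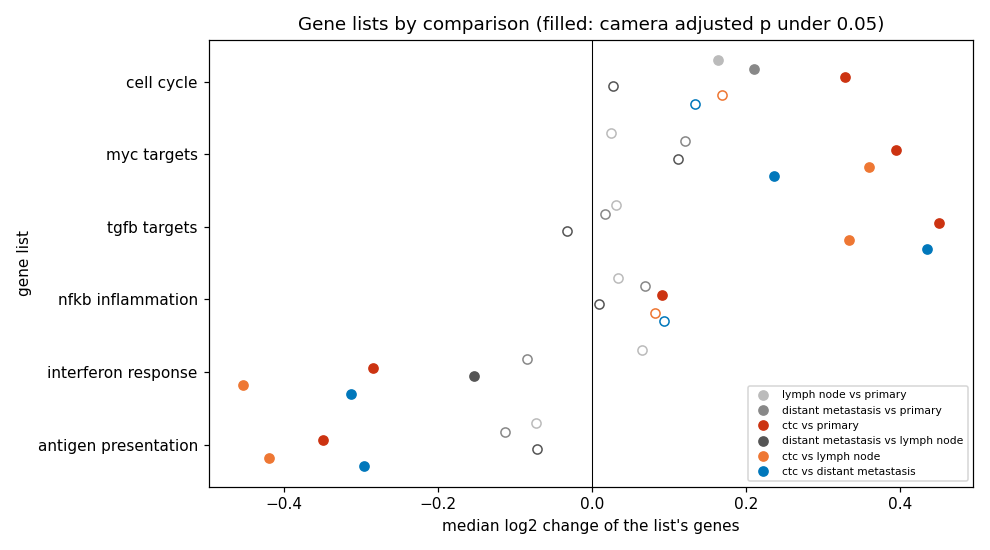
Median log2 change of the genes of 6 lists (horizontal axis) in the 6 comparisons (colors); filled dots mark camera adjusted p under 0.05. The interferon median was -0.29 for CTCs against primary tumors and -0.45 against lymph node metastases, and the TGF-beta medians were 0.45 and 0.33.

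Against lymph node metastases, CTCs had higher IGFBP3, which encodes a carrier of insulin-like growth factors, at 11.08 ± 0.94 against 8.84 ± 0.43 (SD, n = 6; log2 change 2.25, SE 0.40, adjusted p = 0.00856). COXFA4L3, CXCL2, CGB1 and SMAD6 rose by 2.21, 1.93, 1.91 and 1.79 (adjusted p = 0.0362, 0.0145, 0.000465 and 0.024). APOE fell by 4.43 on the log2 scale, from 11.14 ± 1.72 to 6.72 ± 0.76 (adjusted p = 0.031). OLFML2A, the secreted protein gene LGALS3BP, TRIB2 and DLG4 fell by 2.44, 2.06, 1.95 and 1.85 (adjusted p = 0.0353, 0.00588, 0.00905 and 0.0395). All 10 genes moved the same way in 6 of 6 mice. The HBA2 probe lay at 11.45 ± 2.83 in lymph node metastases (log2 change -3.42, adjusted p = 0.38).

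Of 27 interferon genes 4 fell, 0 rose and 23 did not pass in CTCs against lymph node metastases, and 14 fell when adjusted over the list alone. IFIT2, IFIT1, IFI6 and OASL fell by 1.29, 1.71, 1.83 and 0.82 (adjusted p = 0.00314, 0.00856, 0.0109 and 0.0209). The list's adjusted p was 3.15e-09 (adjusted p = 0.377 with an estimated correlation). The mean of the host myeloid list, which passed in no comparison, was 6.43 ± 0.07 in lymph node metastases and 6.24 ± 0.07 in CTCs (SD, n = 6). The antigen presentation list fell, with TAPBP and PSMB8 past the threshold of 19 measured (-1.36 and -1.44, adjusted p = 0.00905 and 0.0451) and 3 when adjusted over the list alone. Their list had adjusted p = 0.00294 (adjusted p = 0.707 with an estimated correlation), and with HBA2 as a covariate adjusted p = 0.0662. The TGF-beta list rose, with 3 of 23 past the threshold (TGFBI 1.78, CCN1 1.65 and SMAD6 1.79; adjusted p = 0.00305, 0.0043 and 0.024) and, adjusted over the list alone, 10 up and 1 down. That list had adjusted p = 0.000898 (adjusted p = 0.247 with an estimated correlation). The MYC target list rose as well, with NPM1 and TFRC past the threshold of 22 (0.34 and 1.30, adjusted p = 0.00856 and 0.046) and 7 when adjusted over the list alone. Their adjusted p was 7.88e-06 (adjusted p = 0.342 with an estimated correlation).

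In this comparison limma called 448 probes, 266 higher and 182 lower in CTCs, in 151 and 136 genes, and the replicate block gave 1041 (579 higher and 462 lower). The share of higher calls was 59.4% here and 48.9% with the trend and robust variance model (171 higher and 179 lower of 350). After cyclic loess it was 42.9% (170 higher and 226 lower of 396). Among calls with a log2 change of at least 1, 33 were higher and 91 lower. With only these 12 arrays in the model the count was 198 and SMAD6, OLFML2A and DLG4 no longer passed, and with HBA2 as a covariate it was 202 and COXFA4L3, CXCL2, SMAD6, APOE, OLFML2A and DLG4 no longer passed. Without lymph node replicates 1, 3, 4 and 6 the count was 278, 185, 249 and 194, and without CTC replicates 1, 3, 4 and 6 it was 215, 1041, 220 and 202. The calls of COXFA4L3, SMAD6, APOE, OLFML2A and DLG4 ended without lymph node replicate 6, and also without other arrays. Of 12 runs with 1 array left out they passed in 3, 9, 5, 4 and 3. The calls of IGFBP3, CXCL2, CGB1, LGALS3BP and TRIB2 held with each array left out.

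Against distant metastases, APOE fell in CTCs from 11.80 ± 1.88 to 6.72 ± 0.76 (SD, n = 6; log2 change -5.08, SE 0.98, adjusted p = 0.0257), ATP2A1, the calcium pump of fast skeletal muscle, from 10.39 ± 2.54 to 5.68 ± 0.08 (log2 change -4.70, adjusted p = 0.0267), and the small heat shock protein gene CRYAB from 10.43 ± 1.87 to 6.04 ± 0.40 (log2 change -4.38, adjusted p = 0.0133). CYCSP52, a pseudogene of cytochrome c, and ETFA, an electron carrier of mitochondrial fatty acid oxidation, fell, with log2 changes of -3.96 and -3.56 (adjusted p = 0.0262 and 0.0197). A CYCSP52 probe can also read the parent gene. The other 3 ATP2A1 probes had log2 changes of -1.365, -0.875 and -0.014 and did not pass (adjusted p = 0.15, 0.185 and 0.98). ATP2A1 and CRYAB averaged 5.68 and 6.04 in CTCs, where the median of all values was 5.93, and ATP2A1 had a log2 change of -0.04 against lymph node metastases (adjusted p = 0.994). COXFA4L3, CGB1, SMAD6, TGFBI and the neuropeptide receptor gene NPFFR2 rose by 2.39, 1.97, 1.81, 1.39 and 1.27 (adjusted p = 0.0389, 0.000568, 0.0355, 0.0273 and 0.0122). All 10 moved the same way in 6 of 6 mice, though in mouse 5 ATP2A1 lay at 5.67 in the distant metastasis and 5.58 in CTCs. The HBA2 probe lay at 13.30 ± 3.63 in distant metastases (log2 change -5.27, adjusted p = 0.181, and 0.014 with the replicate block), and the red cell list, the host list of smallest adjusted p, did not pass (adjusted p = 0.11).

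The TGF-beta list rose in CTCs against distant metastases, with TGFBI and SMAD6 past the threshold, 21 of 23 not passing and, adjusted over the list alone, 8 up and 1 down (adjusted p = 0.000186; adjusted p = 0.225 with an estimated correlation). The other called lists had no member past the threshold over all probes. Among interferon genes IFIT2 and IFI6 had log2 changes of -0.87 and -1.29 (adjusted p = 0.0561 and 0.105; 0.00372 and 0.0314 with the replicate block), and 10 of 27 fell when adjusted over the list alone. Their list fell (adjusted p = 0.000186, and 0.707 with an estimated correlation). The host myeloid list, which did not pass, had a mean of 6.43 ± 0.11 in distant metastases and 6.24 ± 0.07 in CTCs (SD, n = 6). For antigen presentation, B2M and TAPBP had log2 changes of -0.50 and -0.79 (adjusted p = 0.127 and 0.183), and 2 of 19 fell when adjusted over the list alone. This list fell too (adjusted p = 0.0129; adjusted p = 0.791 with an estimated correlation). Its adjusted p rose to at most 0.141 with 1 array left out, the call ending without distant metastasis replicate 2 or CTC replicate 4. With HBA2 as a covariate the interferon and antigen presentation lists had adjusted p = 0.179 and 0.807. MYC target genes rose as a list (adjusted p = 0.000645; adjusted p = 0.707 with an estimated correlation), with 2 of 22 up when adjusted over the list alone and TFRC at a log2 change of 1.13 (adjusted p = 0.122).

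The count here was 167 probes by limma, 81 higher and 86 lower in CTCs, in 48 and 63 genes, and 446 with the replicate block (221 higher and 225 lower). The share of higher calls was 48.5%, and 37.7% after cyclic loess (66 higher and 109 lower of 175), and among calls with a log2 change of at least 1, 13 were higher and 45 lower. With only these 12 arrays in the model 4 probes passed, of CGB5, SH2D4A, TSC22D1 and B4GAT1, and none of the 10 genes above, and with HBA2 as a covariate 26 probes passed and CGB1 alone of the 10. Without all arrays of mouse 5 the count was 251, and TGFBI no longer passed. Without distant metastasis replicates 1, 2, 3, 5 and 6 the count was 70, 46, 55, 258 and 95, and without CTC replicates 1, 2, 3, 4 and 6 it was 75, 111, 482, 51 and 53. The calls of CGB1, NPFFR2 and CRYAB held with each array left out. Those of the other 7 genes ended without distant metastasis replicate 2, and also without other arrays. Of 12 runs with 1 array left out, COXFA4L3 passed in 2, SMAD6 in 3 and TGFBI and ATP2A1 in 5. APOE and CYCSP52 passed in 6 and ETFA in 10.

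**Figure D3:**
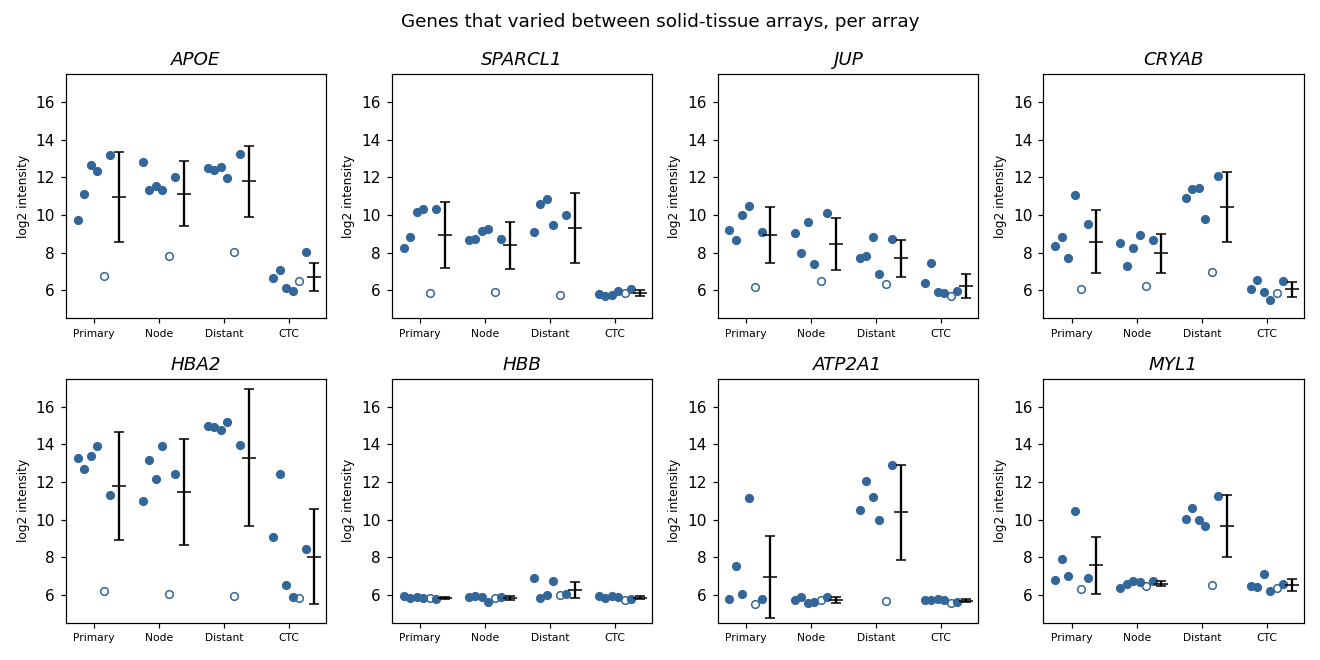
Log2 intensity per array (vertical axis) of 8 genes that varied between solid-tissue arrays, by group (n = 6 each); dots are arrays, open circles the arrays of mouse 5, and black marks the mean ± SD. In distant metastases ATP2A1 lay between 9.96 and 12.92 in 5 arrays and at 5.67 in that of mouse 5, and HBB stayed at or below 6.89 throughout.

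Lymph node metastases differed from primary tumors in no single probe that passed the threshold. IGFBP3 had the largest difference among the 10 genes of smallest p, at 8.84 ± 0.43 against 10.72 ± 1.02 (SD, n = 6; log2 change -1.89, SE 0.40, adjusted p = 1), and NGEF lay at 7.04 ± 0.20 against 6.09 ± 0.36 (log2 change 0.95, adjusted p = 1). GLE1 and FNBP1L had log2 changes of 0.39 and 0.47, and LINC01451, ATP2B2, MIR765, SCARNA2, ELAVL2 and SAMD13 changes between -0.42 and 0.34, all with adjusted p = 1. Cell cycle genes rose as a list by camera with the preset correlation (adjusted p = 3.5e-05) but not with an estimated correlation (adjusted p = 0.791). Fry called 0 lists in this comparison. Genes of a list can move together, so that their estimates are not independent. Of the 30 members, 0 passed the threshold, 0 when adjusted over the list alone, and 27 had estimates above 0 (median log2 change 0.16). Among them UBE2C, CENPE, AURKA and CDC20 had log2 changes of 0.28, 0.40, 0.31 and 0.29. Limma called 0 probes, as it did with the replicate block, with every other setting run and with each array left out, and 1611 probes (3.40%) had an unadjusted p under 0.05.

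Distant metastases likewise had 0 probes called against primary tumors by limma, with and without the replicate block, and 3016 probes (6.37%) had an unadjusted p under 0.05. Of the 10 genes of smallest p, TLE6, a corepressor of the Groucho family, had a log2 change of -0.81 and the collagen gene COL8A2 one of 0.55, and JAML, CCDC200, PAX7, SCARNA2, IZUMO4, ARSH, HYCC1 and MTMR7 had changes between -0.46 and 0.39, all with adjusted p = 0.43. Cell cycle genes rose as a list by camera with the preset correlation (adjusted p = 0.000127) but not with an estimated correlation (adjusted p = 0.879). Fry called 0 lists in this comparison. Of the list's estimates, which are not independent, 29 of 30 lay above 0 (median log2 change 0.21). Past the threshold were 0 members, 0 also when adjusted over the list alone. CENPE and AURKA had log2 changes of 0.66 and 0.35 (adjusted p = 0.577 and 0.758). MYC target genes had adjusted p = 0.0706, and 0.0494 with the replicate block, both at the preset correlation. With an estimated correlation, in the model without the block, 0 lists were called in this comparison. Without distant metastasis replicate 5 the count was 5, with probes of DTNA, ATP2A1, TNNT3 and JAML. Without all arrays of mouse 5 it was 2, both of DTNA, which encodes dystrobrevin (log2 changes 1.65 and 1.57); DTNA and TNNT3 were chosen after their values were seen.

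Between distant and lymph node metastases no probe passed, and the largest differences among the 10 genes of smallest p were those of ATP2A1, MYL1 and NEB, which skeletal muscle expresses. ATP2A1 lay at 10.39 ± 2.54 in distant and 5.72 ± 0.14 in lymph node metastases (SD, n = 6; log2 change 4.67, SE 0.92, adjusted p = 0.351), MYL1, a myosin light chain gene, at 9.68 ± 1.65 and 6.59 ± 0.15 (log2 change 3.09, adjusted p = 0.351), and NEB, which encodes the thin filament protein nebulin, at 7.71 ± 1.27 and 5.62 ± 0.13 (log2 change 2.09, adjusted p = 0.351). DHRS7C, a gene of muscle membranes, had a log2 change of 1.76 (adjusted p = 0.422), and OTP, ABCA9, TMEM154, COL8A2, PURG and OR2A42 had changes between 0.31 and 0.58 (adjusted p from 0.351 to 0.422). The other 3 ATP2A1 probes had smaller log2 changes of 1.26, 0.95 and 0.13 (adjusted p = 0.679, 0.623 and 0.855). The 2 other MYL1 probes had log2 changes of 0.14 and -0.06 (adjusted p = 0.947 and 0.975), and the other DHRS7C probe one of -0.05 (adjusted p = 0.976). In the distant metastasis of mouse 5 ATP2A1, MYL1 and NEB lay at 5.67, 6.51 and 5.64. The list of smooth and skeletal muscle markers did not pass (adjusted p = 0.995), and its median log2 change was -0.04 where its mean was 0.03; its muscle creatine kinase and skeletal actin genes, CKM and ACTA1, lay at 5.59 and 5.78 in distant metastases.

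Interferon genes fell as a list in distant against lymph node metastases by camera with the preset correlation (adjusted p = 0.000186). The list did not pass with an estimated correlation (adjusted p = 0.707), and fry called 0 lists in this comparison. Of its estimates, which are not independent, 24 of 27 lay below 0 (median log2 change -0.15). Past the threshold were 0 members, 0 also when adjusted over the list alone. IFIT3 and IFIT1 had log2 changes of -0.50 and -0.68 (adjusted p = 0.767 and 0.812). Hypoxia genes had adjusted p = 0.102, and 0.0359 with the replicate block, both at the preset correlation. With an estimated correlation, in the model without the block, 0 lists were called in this comparison. Limma called 0 probes with and without the replicate block, and 2818 probes (5.96%) had an unadjusted p under 0.05. Without distant metastasis replicate 5 the count was 11, of ATP2A1, NEB, MYL1, ABCA9, PURG, DHRS7C, CKMT2, MYBPC1, TNNT3 and, with 2 probes, DTNA, and without all arrays of mouse 5 it was 6, of ATP2A1, MYL1, NEB, ABCA9 and, with 2 probes, DTNA.

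The 3 comparisons of CTCs shared 55 higher and 43 lower probes. Between the comparisons with primary tumors and with lymph node metastases, 210 higher and 148 lower probes were called in both, where independent lists would share 3.13 and 1.43. Simulated unchanged groups shared 0, which is no baseline, since few probes are called where nothing changed. The overlaps were 69 and 51 for primary tumors and distant metastases (0.952 and 0.678 for independent lists), and 59 and 45 for lymph node and distant metastases (0.455 and 0.331). These comparisons use the same CTC arrays, so that their lists are not independent. With those arrays divided, 3 for each comparison, the overlaps between primary tumors and lymph node metastases were 26 higher and 23 lower, or 12 and 10 with the parts exchanged. Divided in the same way, the overlaps were 16 and 10, or 7 and 6, for primary tumors and distant metastases, and 7 and 6, or 4 and 5, for lymph node and distant metastases. COXFA4L3, CGB1, SMAD6 and TGFBI were higher and APOE was lower in all 3. Comparisons with the primary tumors shared 0 calls, since those of the metastases held none; across probes, which are not independent, the log2 changes of lymph node and distant metastases correlated at r = 0.431, where unchanged groups gave 0.488 and divided primary arrays 0.0987. Their covariance was 0.00795, against 0.0141 for unchanged groups.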

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

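The choice of HBA2 and the leaving out of mouse 5 in all 3 correlations, the correlation for the probes lower in CTCs, the test of the muscle list, the runs without mouse 5 and the HBA2 covariate came after results were seen. In 27 of 240 groups of 6 values, 1 array lay far from the others, where chance gives about 12 at 1 in 20. Of these, 6 were in lymph node replicate 5, 5 in distant metastasis replicate 5 and 4 in primary replicate 5, all from mouse 5.

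In mouse 5, some probes bright in the other solid tissues were dim, and some probes higher in CTCs were bright: in primary replicate 5, SMAD6, IER3 and P2RY8 lay at 7.69, 11.70 and 7.99 (nearest 6.17, 9.84 and 6.72), and in lymph node replicate 5 COXFA4L3 lay at 9.90 (nearest 8.45). APOE lay at 7.83 in lymph node replicate 5 (nearest other 11.31) and 8.05 in distant metastasis replicate 5 (nearest 11.99), SPARCL1 at 5.89 (nearest 8.66) and 5.75 (nearest 9.09), and HBA2 at 6.20, 6.04 and 5.93 in its primary tumor, lymph node and distant metastasis. APOE and SPARCL1 were also dim in CTCs, at no more than 8.03 and 6.06, while HBA2 reached 12.43 in CTC replicate 2, and less mouse RNA in an array is a candidate explanation for the dim probes. Over the 15 solid-tissue arrays of the other mice, deviations from the group means were correlated, so that differences between groups did not enter. Arrays of 1 mouse are not fully independent. HBA2 lay between 10.99 and 15.21 in these 15 arrays, so the low values of mouse 5 and of most CTC arrays were not covered. The correlations, here and for the lists below, could therefore miss a relation that shows only at low HBA2. The mean deviation of the 373 probes lower in CTCs had no detected correlation with that of HBA2 (r = 0.0844, permutation p = 0.764, rho = -0.05, permutation p = 0.867, and r = -0.38 without the 2 arrays farthest from the median). Nor did that of the 556 probes higher in CTCs (r = 0.0661, permutation p = 0.792, rho = 0.232, permutation p = 0.377, and r = 0.494 without those 2). Adjusted over the 3 relations computed, p was 0.823 for each r and 0.996 for each rho; less host RNA and a change within the tumor cells cannot be told apart for these probes, because neither correlation passed a test and the species share of a probe's signal was not measured.

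The interferon and antigen presentation lists were lower in CTCs than in primary tumors, with 3 of 27 and 3 of 19 genes past the threshold and, for each list, adjusted p = 0.707 with an estimated correlation. With HBA2 as a covariate both lists still passed against primary tumors by camera with the preset correlation (adjusted p = 0.000623 and 0.0232). Over the alternatives their adjusted p ranged from 4.42e-07 and 7.59e-05 to 0.707. The IFI6 probe of higher mean still passed (log2 change -1.52, adjusted p = 0.0297, against -1.92 and 0.00555 without the covariate). The other IFI6 probe did not pass at all (log2 change -0.75, adjusted p = 0.129). Against distant metastases both lists lost their calls with that covariate, as did the antigen presentation list against lymph node metastases. The covariate removes only what follows HBA2, so these calls do not decide between the causes. Within groups, the mean deviation of the 46 genes of both lists had no detected correlation with that of HBA2 over the same 15 arrays (r = -0.0482, permutation p = 0.823, rho = 0.00357, permutation p = 0.996, and r = -0.264 without the 2 farthest arrays). Less host RNA and lower expression in the tumor cells cannot be told apart for the lists, since the correlation reached no threshold in either direction and host RNA that HBA2 does not follow was not removed. A difference of the tissue itself, which the groups name, stays open and untested, and myeloid markers such as AIF1 (log2 change -2.02, adjusted p = 0.0591; 0.00455 with the replicate block) were not set against these lists.

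Of the genes of smallest p between distant and lymph node metastases, 1 probe of the muscle gene ATP2A1 lay between 9.96 and 12.92 in 5 distant metastases, at 5.67 in replicate 5 and at 11.17 in primary replicate 4 (nearest 7.53). The other 3 ATP2A1 probes had log2 changes of 1.26, 0.95 and 0.13 in distant against lymph node metastases and did not pass. Muscle RNA in these arrays is a candidate explanation for ATP2A1, MYL1 and NEB. Without distant metastasis replicate 5, the striated muscle genes CKMT2, MYBPC1 and TNNT3, named after their values were seen, also passed against lymph nodes (log2 changes 2.90, 1.48 and 1.02; adjusted p = 0.0332, 0.04 and 0.0113). The fixed muscle list did not pass (adjusted p = 0.995), and its CKM and ACTA1 lay at 5.59 and 5.78, but 5 of its 18 genes had a mean above 5.93 in CTCs and 1 (TAGLN) is in another list, so that most of the list was near the bottom of the scale. Muscle RNA and expression by the tumor cells cannot be told apart for these genes, since human probes of the list may read mouse RNA poorly.

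Other arrays far from their group were as follows. IGFBP3 lay at 12.74 in primary replicate 1 (nearest 10.55) and at 9.22 in distant metastasis replicate 5 (nearest 9.63). NGEF lay at 7.09 in CTC replicate 2 (nearest 6.31), FNBP1L at 10.73 in lymph node replicate 1 (nearest 10.25) and IZUMO4 at 5.95 in distant metastasis replicate 5 (nearest 5.78). IFI6 lay at 9.83 (nearest 10.92), GSTO2 at 8.31 (nearest 8.98) and CYCSP52 at 7.29 (nearest 8.94) in lymph node replicate 5. TGFBI lay at 6.63 in distant metastasis replicate 6 (nearest 7.47) and 7.65 in CTC replicate 3 (nearest 8.89), and NRG1 at 7.42 in distant metastasis replicate 6 (nearest 9.11). OTP lay at 6.78 in distant metastasis replicate 2 (nearest 6.55), MYL1 at 6.51 in distant metastasis replicate 5 (nearest 9.68) and DHRS7C at 7.24 in primary replicate 4 (nearest 5.84). OR2A42 lay at 7.05 in distant metastasis replicate 3 (nearest 6.56) and 6.70 in CTC replicate 5 (nearest 6.43). The mean of the antigen presentation list was 8.28 in primary replicate 5 (nearest 8.71), and that of the MYC target list 10.64 in CTC replicate 3 (nearest 11.09).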

How the results depend on the processing

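The runs without mouse 5, with the HBA2 covariate, with cyclic loess and of similarity over brighter probes were chosen after the data were seen. The direction of all 70 named values (63 with the filter, which left out the others) held in every setting run, leave-outs included, where 139 of 840 values missed the threshold and 7 came to pass it; 29 missed the threshold with only the groups compared in the model, 25 with the HBA2 covariate, 2 with the trend and robust model (SPARCL1 against primary tumors and COXFA4L3 against distant metastases) and 1 without mouse 5, which brought 4 past it. Lymph node metastases against primary tumors stayed at 0 called probes in every setting run. In the order CTCs against primary tumors, lymph nodes, distant metastases and the F test, the fixed replicate block gave 1659, 1041, 446 and 880 probes, of which 912, 443 and 164 in the pairwise comparisons were shared with the model without it; it added 2 list calls (MYC targets, distant against primary; hypoxia, distant against lymph node) and changed no other list call and none of the calls of the 70 named values. Among list members whose adjusted p is given, it ended the call of FOSL1 against primary tumors and brought CRYAB, HBA2, AIF1, C1QA and CORO1A against primary tumors, and HBA2, IFIT2 and IFI6 against distant metastases, past the threshold. The random replicate block gave 255 for distant metastases. Array weights gave 1487 and 790, and 678 for the F test. Only the groups compared gave 163, 198 and 4. The filter on probes above the median gave 742 for lymph nodes. The HBA2 covariate gave 530, 202, 26 and 143, and a log2 change of at least 1 gave 208, 124, 58 and 153, which by construction are fewer. Without mouse 5 the count was 251 for CTCs against distant metastases, 2 for distant metastases against primary tumors and 6 against lymph nodes. The mean of a gene's probes gave 499 genes for CTCs against lymph nodes, where the probe of highest mean gave 287. Over all 39 lists in the 6 comparisons, where camera called 17, camera with an estimated correlation called 0, fry 6 (5 up and 1 down) and mixed fry 56. The difference in similarity was 0.00153 with Pearson's r and 0.00427 over brighter probes (permutation p = 0.105 and 0.0661). With 1 array left out, counts ranged from 399 (without primary replicate 3) to 1662 (without CTC replicate 3), from 185 (without lymph node replicate 3) to 1041 (without CTC replicate 3), from 46 (without distant metastasis replicate 2) to 482 (without CTC replicate 3) and, for the F test, from 150 (without CTC replicate 6) to 833 (without CTC replicate 3). They ranged from 0 to 5 for distant metastases against primary tumors and from 0 to 11 against lymph nodes, both highest without distant metastasis replicate 5, and from 16 to 21 for lists. The cause was not tested. Not run were the background corrections (none, normexp with an offset, neqc with other scalings), the filters on detection p and the slide as a block, since they need the signal columns not used here. The number of arrays limits precision, and dim probes near the bottom of the scale can hide changes.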

Other observations

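The tests on divided samples were set before the data were examined. Among 23 genes of stem cells and circulating tumor cells, CD44, the hyaluronan receptor, rose in CTCs against primary tumors from 12.63 ± 0.46 to 13.44 ± 0.24 (SD, n = 6; log2 change 0.81, adjusted p = 0.0356, higher in 5 of 6 mice). The laminin-binding integrin gene ITGA6 rose by 0.91 (adjusted p = 0.0409, higher in 6 of 6 mice), and CD47, which encodes a signal against phagocytosis, fell by 0.56 on the log2 scale (adjusted p = 0.0164, lower in 6 of 6 mice). CD47 also fell by 0.53 against lymph node metastases and by 0.64 against distant metastases (adjusted p = 0.034 and 0.0197). The other 20 members did not pass against primary tumors, 3 rose and 2 fell when adjusted over the list alone, and the list did not pass (adjusted p = 0.767).

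Of 29 collagen and matrix genes, the laminin chain genes LAMA5 and LAMC1 fell in CTCs against primary tumors by 1.05 and 0.52 on the log2 scale (adjusted p = 0.0088 and 0.0446), and LAMA5 fell by 1.21 and 1.12 against lymph node and distant metastases (adjusted p = 0.00588 and 0.017). The list did not pass (adjusted p = 0.53, 0.0715 and 0.0715), and adjusted over the list alone 1 rose and 2 fell against primary tumors. The chaperone genes HSP90AA1 and HSPD1 rose against primary tumors by 0.66 and 0.70 (adjusted p = 0.0339 and 0.0407), while CRYAB of the same list had a log2 change of -2.54 (adjusted p = 0.0816) and passed with the replicate block (adjusted p = 0.0192, lower in 6 of 6 mice). The heat shock list of 16 did not pass (adjusted p = 0.668; 2 rose and 1 fell when adjusted over the list alone), with a median log2 change of 0.16 and a mean of -0.11. FOSL1, an AP-1 subunit gene, rose by 1.24 (adjusted p = 0.0444), a call that ended with the replicate block (adjusted p = 0.063), and PFKFB3, an activator of glycolysis, rose by 0.94 against primary tumors and 0.85 against lymph node metastases (adjusted p = 0.00761 and 0.0193).

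The counts in CTCs were set against those of other divisions of the arrays, with all 24 arrays in the model. The real division gave the most calls each time, but 1 of 100 or 1 of 32 is the lowest share this test can give. With only the 12 arrays of a comparison in the model, the real counts were 163, 198 and 4 against primary tumors, lymph node and distant metastases. Other divisions were not run in that model. Of 100 splits of the 12 arrays, 1, the real one, gave as many as 929 probes between CTCs and primary tumors, and the highest other gave 329. For CTCs against lymph node metastases 1 of 100 splits gave 448, with 88 as the highest other, and against distant metastases 1 of 100 gave 167, with 91 as the highest other. For the F test 1 of 100 splits of the 24 arrays gave 402, with 44 as the highest other. Of the 32 splits that put 1 array of each mouse on each side, only the real 1 gave as many in these 3 comparisons, and the highest others gave 8, 4 and 5.

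For the comparisons with 0 called probes this count says nothing about chance, since any split, and so all 100 and all 32 that part every mouse, gives at least 0. The highest other split gave 1 probe for lymph node metastases against primary tumors, 181 for distant metastases against primary tumors and 106 for distant against lymph node metastases. Of the splits other than the real one, 2, 7 and 5 called any probe. For the many calls of single splits the mouse is a candidate explanation. With every mouse parted, 1, 0 and 1 of the other splits called any probe, and the highest others gave 1, 0 and 1. These counts do not tell the 2 kinds of split apart, since only 32 splits part every mouse, against 100 of the other kind. Arrays of the same mouse number deviated together (mean correlation 0.138 against -0.0253, permutation p = 0.0099).

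In the other correlations with the primary tumors shared, log2 changes across probes correlated at r = 0.339 for lymph node metastases and CTCs (0.487 for unchanged groups, 0.193 with the primary arrays divided) and at r = 0.502 for distant metastases and CTCs (0.485 and 0.228). Their covariances were 0.0102 and 0.0204, against 0.014 and 0.0138 for unchanged groups. Probes are not independent replicates.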
